A study of Mus musculus with 2 samples.

How the data were processed

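Whole brain DNA of C57BL/6 mice was sequenced after bisulfite conversion, in 1 wild-type and 1 MeCP2 knockout library. Per the labels' protocols, DNA was sheared by ultrasound, converted with a commercial bisulfite kit and made into libraries with a kit that adds adapters after conversion. Reads were aligned with BSMAP to mm9, per the submitters' processing notes. The BSMAP version and the program that counted methylated reads per CpG are not given in the sources used here. Names of the deposited tables state that duplicate reads were filtered. The authors' deposited tables give, per the file headers, a count of covering reads and a count of methylated reads for each CpG, pooled and on each strand. They also give the methylated fraction of reads per CpG, per the file headers. In every row the pooled counts equalled the sum of the strands and the fraction equalled the ratio of the counts within 0.0006, so levels were recomputed from the counts and the deposited fraction was not used further. Bisulfite sequencing does not separate methylcytosine from hydroxymethylcytosine, which is common in brain.

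Depth sets the precision. The wild-type library held 175740559 reads over CpGs and the knockout library 152898499. At a median of 7 and 6 reads a single CpG is measured coarsely, so most comparisons used sums over tiles or regions. Intervals are 95% Wilson intervals or jackknife standard errors over blocks of 10 Mb and cover no spread between animals. Reads were not marked by molecule. Sums of reads over CpGs count a read again for each CpG it covers. They can therefore exceed the number of separate reads, and Wilson intervals on them are too narrow.

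Libraries were grouped by the genotype in the labels. The level of a library is methylated reads over all reads, in percent, and differences are knockout minus wild type in percentage points. The genome-wide level used all listed CpGs. CpG shares used CpGs with at least 10 reads in both libraries. Tiles were 1000 bp long with at least 3 CpGs read in both libraries and at least 50 reads per library. A two-sided Fisher's exact test compared methylated and unmethylated reads per tile, with Benjamini-Hochberg adjustment over autosomal tiles (X and Y separately). A tile was called at an adjusted p under 0.05 and a difference of at least 20 points. Lost and gained CpGs were at least 80% methylated in one library and at most 5% in the other. The named tiles are the 10 largest gains and the 10 largest losses among called autosomal tiles. These rules and the alternatives to them were set before the data were examined, with named tiles as the rule for a build without annotation.

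Other measures were added after the data were seen. CpG-dense regions were built from CpGs that had at least 20 listed CpGs, themselves included, in the 500 bp centred on them. Such CpGs were joined where the next lay within 200 bp, and a region ran from the first to the last of them, so it can be shorter than 500 bp and hold fewer than 20 CpGs. Regions of at least 200 bp with at least 3 CpGs read in both libraries and 50 reads per library were tested like tiles. Runs without reads in one library needed at least 20 CpGs and 60 reads in the other, a limit fixed after a first look with fewer CpGs. Strand comparisons needed at least 25 reads per strand and library, and comparisons of alternate CpGs within a tile at least 10. The coverage limit of 35 reads (wild type) and 30 reads (knockout) is the 99.9th percentile; leaving out CpGs above it was foreseen for the genome-wide level and the tiles and added for other values. Classes of local CpG density counted CpGs within 250 bp on either side.

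Tile calling was tested on simulated counts drawn for the 1018834 tested tiles with independent reads. Of 50 tiles each changed by 20, 30, 40 and 50 points it recovered 10, 42, 82 and 96%, and it called 2 unchanged tiles. Recovery at 20 points is low in part because the change equals the threshold. Far fewer tiles passed than in the data, so the adjusted p was harder to reach and these shares do not give recovery in the data. Changed tiles were drawn only from intermediate levels, so recovery at low and high levels was not simulated. Thinning used a fixed seed. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

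No gene annotation on mm9 was used here, and coordinates were not converted between builds. The planned results on promoters, gene bodies, gene lists (cell type markers included), gene length and annotation classes were therefore not analysed here. Coverage of Mecp2 was replaced by the genome-wide search for runs without reads.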

Results

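CpG methylation was measured by whole genome bisulfite sequencing in whole brain DNA of C57BL/6 mice, in 1 wild-type library and 1 library from a MeCP2 knockout. MeCP2 is a nuclear protein that binds methylated CpGs and is abundant in neurons. Its gene lies on the X chromosome. The comparison asked where CpG methylation differed in brain DNA that lacked this reader of methylation. The wild-type library held 175740559 reads over 21163798 CpGs, with a mean coverage of 8.30 and a median of 7 reads per CpG (quartiles 5 and 10). The knockout library held 152898499 reads over 21082381 CpGs, with a mean of 7.25 and a median of 6 (quartiles 4 and 8). Coverage reached 10 reads at 26.9% of the listed wild-type CpGs and at 16.5% of the listed knockout CpGs. Both libraries listed 20952013 CpGs in common. With 1 library per genotype no value below has a replicate check, and each test compares these libraries and not the conditions. Wilson intervals cover counting error only. Jackknife standard errors cover variation between blocks of 10 Mb along the genome, and no interval covers spread between animals. Read numbers are sums over CpGs, so a read that covers several CpGs is counted several times. Positions are mm9, counted from 1, and gene annotation on this build was not used here.

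The longest stretch of CpGs that the wild-type library covered and the knockout library did not lay on the X chromosome. From X 71280563 to X 71283136, a span of 2574 bp with 42 CpGs, the wild-type library held 125 reads, 84.8% of them methylated, and the knockout library held 0. The ratio of knockout to wild-type reads over the X chromosome, 0.872, predicted 109 knockout reads there. With independent reads, a count of 0 would allow up to 3 reads, or 2.75% of the predicted number. These reads are counted per CpG and neighbouring CpGs can share a read, so that limit is too low. The nearest CpGs read in the knockout library lay at 71279671 and 71283205. In the 10000 bp to the left the wild-type library held 192 reads and the knockout library 145, and in the 10000 bp to the right they held 144 and 115. In all, 339 runs of at least 20 CpGs, 16 of them on X, had no knockout read while the wild-type library held at least 60 reads; the next longest spanned 829 bp. In the opposite direction 98 runs were found, 8 of them on X, the longest 687 bp. The other runs were short and CpG dense, with a median of 14.8 CpGs per 100 bp among the knockout runs against 1.63 in the X stretch. The search was genome-wide and designed after the data were seen; whether the stretch lies within Mecp2 was not determined here.

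**Figure D1:**
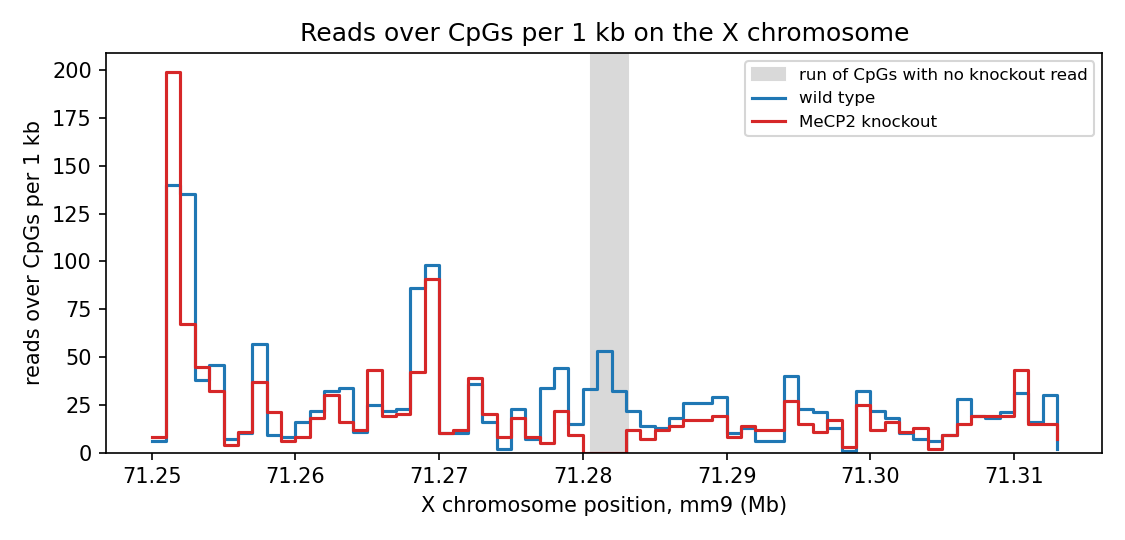
Reads over CpGs per 1 kb (vertical axis) along the X chromosome in Mb of mm9 (horizontal axis), for the wild-type library (blue) and the MeCP2 knockout library (red). The grey band marks the 2574 bp with 125 wild-type reads and 0 knockout reads.

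Brain CpGs were methylated to the same level in both libraries within the error of the difference. Of all reads over CpGs, 76.6877% were methylated in the wild-type library (95% Wilson interval 76.6814 to 76.6939) and 76.6812% in the knockout library (76.6745 to 76.6879). The difference of -0.00646 percentage points had a jackknife standard error of 0.0586 over 277 blocks of 10 Mb. Without CpGs of very high coverage, above 35 reads in the wild-type or 30 reads in the knockout library, the knockout library was higher by 0.0973 points (standard error 0.0107). CpGs above the limit of a library held 8.99% of its reads in the wild type and 9.68% in the knockout. Over all covered CpGs the knockout level was the higher on 14 of 19 autosomes, with differences from -0.387 points on chromosome 9 to 0.221 on chromosome 18. With high-coverage CpGs left out it was the higher on 18 of 19, from -0.00697 on chromosome 16 to 0.218 on chromosome 18. With each CpG weighted equally it was the higher on 11 of 19, from -0.0399 on chromosome 16 to 0.103 on chromosome 7. That count left out high-coverage CpGs and used only CpGs with at least 5 reads in both libraries, so the set of CpGs differed too. Mitochondrial CpGs, 287 in number, had 0.297% methylated reads in the wild-type library (Wilson interval 0.286 to 0.307) and 0.296% in the knockout library (0.285 to 0.307).

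**Figure D2:**
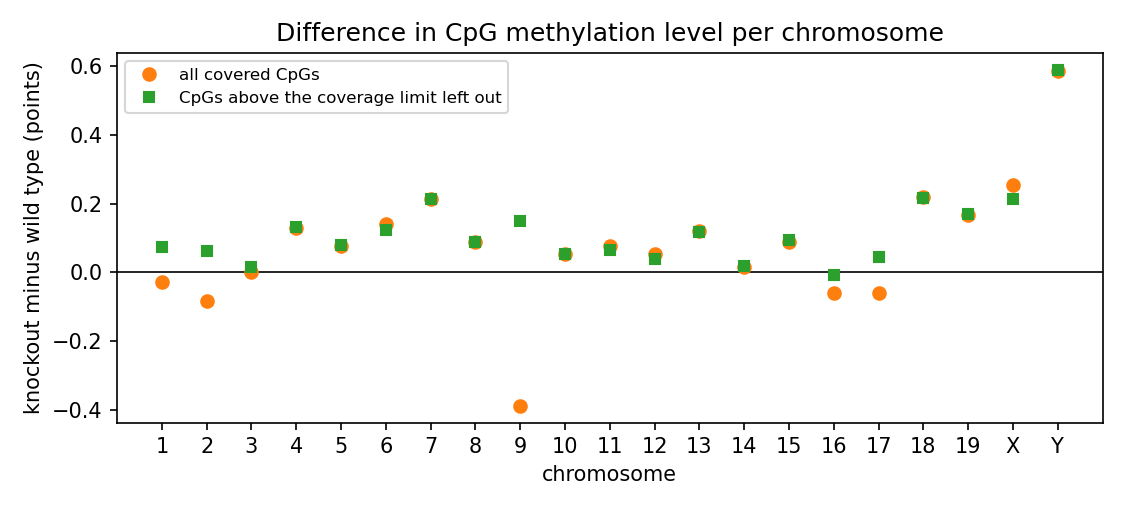
Knockout minus wild-type methylation level in percentage points (vertical axis) for each chromosome (horizontal axis), over all covered CpGs (circles) and without CpGs above the coverage limit (squares). The lowest circle is chromosome 9 at -0.387, whose difference turned positive without the high-coverage CpGs.

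The split of CpGs into low, intermediate and high methylation was also alike. Among 1457059 CpGs read at least 10 times in both libraries, 4.92% of wild-type and 4.90% of knockout CpGs lay below 20%. Intermediate levels, from 20 to 80%, were found at 36.0% and 36.3%, and levels above 80% at 59.1% and 58.8%. The knockout minus wild-type share of high CpGs was -0.248 points, and it was 0.437 points among the 40514 CpGs read at least 20 times. Shares of this kind depend on read depth, which was lower in the knockout library.

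Autosomal sequence in 1 kb tiles followed the diagonal, with no gain or loss at the median tile in the knockout library. Of 1018834 tiles tested, 538 were higher and 609 lower in the knockout library by at least 20 percentage points (two-sided Fisher's exact test on reads, Benjamini-Hochberg adjusted), together 0.113%. The median difference over all tiles was 0 and its SD 6.71 points. Pearson's r of the levels across tiles, which are not independent replicates, was 0.939. Of the 1147 called tiles 994, or 86.7%, lay between 20 and 80%, against 33.9% of tested tiles. The required 20 points leave little room for calls near 0 or 100%, so this share does not show where methylation differed. Reads of neighbouring CpGs can come from the same DNA fragment, so they are not independent and these p-values are too small.

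**Figure D3:**
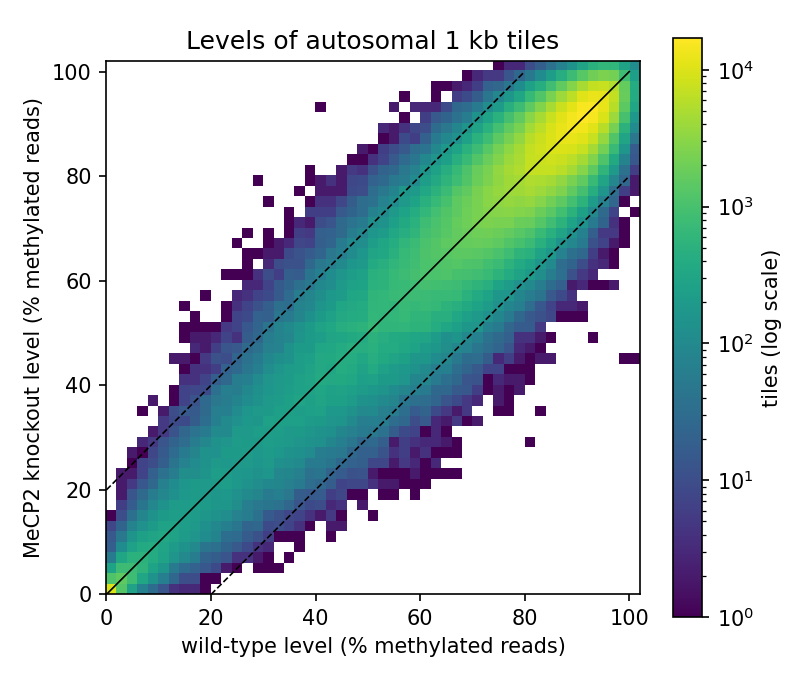
Methylation level of autosomal 1 kb tiles in the wild-type library (horizontal axis) and the MeCP2 knockout library (vertical axis), both in % methylated reads, with colour for the number of tiles on a log scale. The solid line marks equal levels and the dashed lines 20 points of difference; r across tiles was 0.939.

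Across tiles as a set, differences seen on the plus strand did not recur on the minus strand. CpG methylation is read on each strand from separate reads, so the knockout minus wild-type difference can be measured once per strand. Over 754216 tiles with at least 25 reads per strand in each library, without high-coverage CpGs, the differences of the strands had a Pearson's r of -0.000871 (jackknife standard error 0.00129), while the wild-type levels of the strands had an r of 0.899. The covariance of the strand differences left room for differences shared by the strands with an SD of at most 0.376 points (upper 95% bound), against 6.47 points for the SD of the differences themselves. In windows of 10 kb r was -0.00549 (standard error 0.00237), in windows of 100 kb -0.00411 (0.00780) and in windows of 1000 kb 0.0552 (0.0233). With high-coverage CpGs kept, 1274 of 756204 tiles were called on plus-strand reads, with a median size of 34.5 points. On the minus strand 48.7% of them had the same sign (standard error 1.40), and their median difference in the called direction was -0.180 points (standard error 0.424). On minus-strand reads 1185 tiles were called; 14 tiles were called alike on both strands and 10 oppositely. The same tiles compared between strands within a library gave 4451 calls in the wild-type and 3857 in the knockout library, of which 885 were alike in both. This comparison of strands was chosen after the data were seen, except that a strand control was foreseen.

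**Figure D4:**
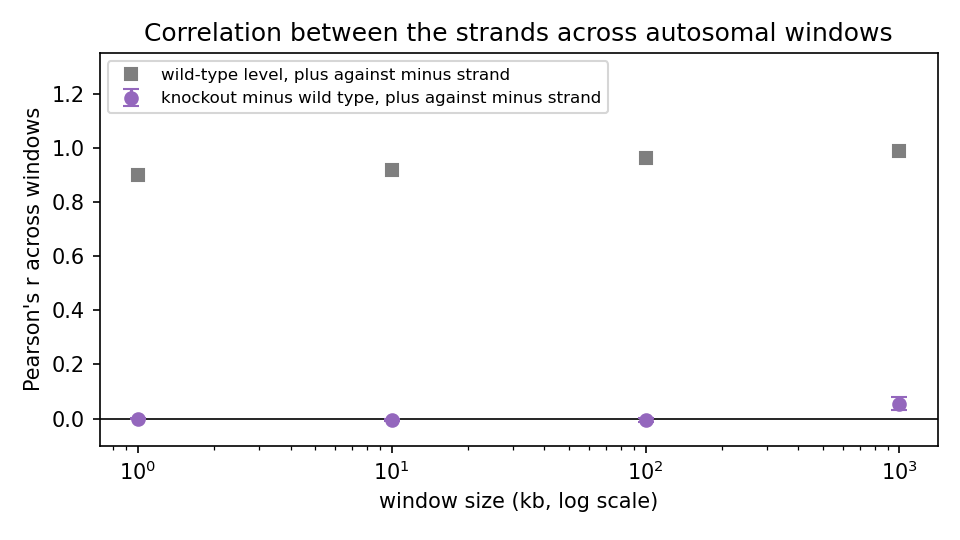
Pearson's r across autosomal windows (vertical axis) by window size in kb on a log scale (horizontal axis): circles compare knockout minus wild-type differences on the plus and minus strands, with bars of 1 jackknife standard error, and squares compare the wild-type levels of the strands. The circles lie between -0.00549 and 0.0552 and the squares between 0.899 and 0.988.

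The 10 tiles with the largest gains in the knockout library came from several chromosomes. The largest was at chromosome 2, 72877001 to 72878000, at 40% of 50 reads in the wild-type and 93.0% of 71 reads in the knockout library (adjusted p = 3.74e-06, Fisher's exact test). Its gain came mainly from the minus strand, at 61.2 points, with 5.59 points on the plus strand. It was followed by the tiles starting at 72456001 on chromosome 1 (29.9% to 78.0%), 9921001 on chromosome 12 (30.8% to 75.5%) and 41434001 on chromosome 15 (38.6% to 80.9%). The next were 114546001 on chromosome 11 (24.0% to 66.0%), 3732001 on chromosome 12 (36.4% to 77.6%), 54620001 on chromosome 11 (27.8% to 68.9%) and 116826001 on chromosome 10 (38.8% to 79.7%). The list ended with 31398001 on chromosome 3 (15.3% to 55.6%) and 173994001 on chromosome 1 (30% to 69.6%). Among the 10, the tile at 54620001 on chromosome 11 had the most reads, 299 and 235, and the smallest adjusted p, 5.68e-17. Its gain came from the plus strand, at 40.7 points, with -0.448 points on the minus strand. At 9921001 on chromosome 12 the plus strand differed by -9.52 points and the minus strand by 51.8 points.

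Among the losses, the tile at chromosome 8, 83239001 to 83240000, went from 100% of 67 wild-type reads to 45.1% of 51 knockout reads (adjusted p = 5.24e-09, Fisher's exact test). The tile at 15395001 on chromosome 4 went from 81.9% of 105 reads to 28.8% of 125, with -57.8 points on the plus and -49.6 points on the minus strand. Next came 46065001 on chromosome 13 (98.1% to 45.2%), 97651001 on chromosome 8 (82.5% to 34.8%), 8528001 on chromosome 12 (67.5% to 23.1%) and 90256001 on chromosome 2 (92.2% to 48.1%). The remaining 4 were 112469001 (76.7% to 34.0%), 111805001 (81.9% to 40.5%) and 39271001 (64.2% to 23.0%) on chromosome 5, and 71784001 on chromosome 1 (86.0% to 44.4%). The tile at 90256001 on chromosome 2 differed by 12.5 points on the plus strand and by -48.0 on the minus strand. At 46065001 on chromosome 13 the plus strand differed by -5.88 points and the minus strand by -63.5 points. With the deeper library thinned, the tile at 8528001 on chromosome 12 lost the call, at a difference of -40.4 points. The sign was the same on both strands in 8 of the 10 gains and 9 of the 10 losses. The tiles were chosen on the pooled difference, which favours such agreement, so this is not independent evidence.

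CpG-dense regions, found from the spacing of the listed CpGs after the data were seen, had nearly equal median levels in both libraries. Of 34228 autosomal regions tested, 15330 lay under 10% methylation in the mean of both libraries, with median levels of 0.649% in the wild-type and 0.654% in the knockout library. A mean under 10% leaves no room for a difference of 20 points, so this class could hold no call. Another 15840 lay over 65%, with medians of 92.1% and 92.2%. In all, 105 regions were higher and 87 lower in the knockout library by at least 20 points. The largest gain, named after its value was seen, was at chromosome 8, 123834891 to 123835136, from 8.85% of 113 reads to 60.8% of 79 reads, with 52.0 points on the plus and 46.1 points on the minus strand. The largest loss, named likewise, was at chromosome 9, 106991917 to 106992154, from 75.8% of 91 reads to 31.8% of 107 reads, with -50.8 and -38.6 points on the strands. Of the 192 called regions 166 had the same sign on both strands, which choosing them on pooled reads favours. Some of the large differences came mainly from one strand: chromosome 8, 126335047 to 126335325, differed by -53.9 points on the plus and -3.30 on the minus strand, and chromosome 7, 117402533 to 117402828, by 1.30 on the plus and 38.3 on the minus strand. The pooled level of all dense regions was 0.737 points higher in the knockout library. By class it was -0.00128 points under 10% and 0.552 points in the 1773 regions from 10 to 35%. It was 0.103 points in the 1285 regions from 35 to 65% and 0.0931 points over 65%. No class reached 0.737 points, so part of the pooled value came from how reads were distributed over the classes. Knockout reads per wild-type read were 0.856, 0.873, 0.841 and 0.889 in these classes, in the same order.

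Dense regions at intermediate levels, a class that includes sequence methylated on a single parental allele, differed in both directions. In the 1285 regions with a mean of both libraries from 35 to 65%, 629 were higher and 656 lower in the knockout library, with a median difference of -0.381 points and an SD of 11.7 points. By the test and at least 20 points, 40 were called higher and 37 lower. A narrower class of 426 regions had at least 25 CpGs and lay between 35 and 65% in each library. That condition removes regions that moved out of the band and limits differences to 30 points, so its spread and calls are set in part by the filter. Its median difference was -0.0395 points (-0.388 for 40 to 60%), and 1 region was called higher and 3 lower. These 4 were named after their values were seen: chromosome 19, 3083347 to 3083886 (42.8% to 63.3%), and on chromosome 15 the regions 80225547 to 80226135 (58.6% to 38.6%), 85337984 to 85338351 (59.7% to 37.3%) and 96884722 to 96886361 (63.1% to 42.6%). Each had the same sign on both strands. Of the 5 regions with the most CpGs, also picked after the data were seen, the pair at chromosome 12, 81858345 to 81860601 (40.1% to 52.1%, adjusted p = 0.000445, Fisher's exact test), and chromosome 7, 150644797 to 150647503 (35.4% to 44.5%, adjusted p = 0.00768), passed the adjusted p but not the 20 points.

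Both libraries were read on the Y chromosome, without high-coverage CpGs at 0.683 of the autosomal mean coverage in the wild-type and 0.690 in the knockout library. The X chromosome was read at 0.566 and 0.573 of it. Over the same CpGs, X methylation was 78.0% in the wild-type and 78.3% in the knockout library, and Y methylation was 74.8% and 75.4%. Of 11279 tiles tested on X, 6 were higher and 5 lower in the knockout library. The 5 lower tiles, named after their values were seen, started at 8346001 (89.7% to 57.1%), 28151001 (87.6% to 66.3%), 35542001 (43.4% to 7.89%), 51028001 (98.4% to 66.7%) and 79454001 (93.6% to 64.2%). Among the 6 higher tiles, those at 11706001 (9.09% to 45%) and 11710001 (5.11% to 40.5%) lay close together and were higher on both strands. Those at 20447001 and 122446001 were also higher on both. The tile at 50338001 differed by -8.92 points on the plus and 19.9 on the minus strand, and that at 135975001 by 33.0 and 1.52. None of 491 tiles on Y was called by Fisher's exact test, and 34 had an unadjusted p under 0.05.

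At a coverage of at least 10, few single CpGs were methylated in one library and unmethylated in the other. Among the 1457059 CpGs read at least 10 times in both libraries, 4 went from at least 80% in the wild-type to at most 5% in the knockout library, and 4 went the other way. Chosen after their values were seen, the lost CpGs were 129685635 on chromosome 1 (8 of 10 wild-type reads methylated, 0 of 12 knockout reads), 117813289 on chromosome 2 (8 of 10, 0 of 12), 40454028 on chromosome 4 (10 of 12, 0 of 10) and 125965412 on chromosome 4 (8 of 10, 0 of 10). The gained CpGs were 172042605 on chromosome 1 (0 of 10 wild-type reads, 8 of 10 knockout reads), 63969788 on chromosome 2 (0 of 11, 10 of 12), 44052854 on chromosome 5 (0 of 10, 9 of 10) and 96562536 on chromosome 7 (0 of 13, 8 of 10). No lost or gained CpG was found on X at this coverage, where 16157 CpGs were read. Lower minimums, added after the data were seen, gave 1335 lost and 1124 gained of 13358721 CpGs at a coverage of at least 5, and 7963 lost and 5928 gained of 18540993 CpGs at 3. On X they gave 43 lost and 23 gained CpGs at 5, and 691 and 577 at 3. The excess of lost over gained CpGs was not tested, and the knockout library was the shallower.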

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

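Alternatives for dense regions, X windows and single strands of the named tiles were chosen after the data were seen. So were the lower minimums for runs without reads and lost or gained CpGs, and the autosomal values at limited coverage or equal weights. With 1 library per genotype and no shared number in the labels, nothing could be paired or left out. Alternatives that need annotation on mm9 (promoters, gene bodies, gene lists, gene length and annotation classes) were not run. The genome-wide difference, -0.00646 points, had a standard error of 0.0586. It was -0.115 at a coverage of at least 5 (standard error 0.0711), -0.369 at 10 (0.315), 0.0590 (0.0143) with each CpG of at least 10 reads weighted equally and 0.0973 (0.0107) without high-coverage CpGs. It was 0.0229 on the plus and -0.0367 on the minus strand, with no standard error computed. On autosomes it was 0.0382 (0.0348), 0.0935 (0.0109) without high-coverage CpGs and 0.0130 (0.00683) with each CpG of at least 5 reads weighted equally. The values more than 2 standard errors from 0 were all positive, and the negative values that have one lay within 2. The cause was not tested, except for the weighting and density tests on autosomes. The share of CpGs under 20% differed by 0.0564 points at a coverage of 5 and -0.146 at 20, that of intermediate CpGs by -0.291 at 20, and that of high CpGs by -0.375 at 5 and 0.437 at 20; the cause was not tested. Called tiles, 538 higher and 609 lower, became 775 and 915 with 500 bp tiles, 26 and 19 with 5 kb tiles, 139 and 149 at 30 points, 344 and 388 with the deeper library thinned, and 250 and 256 where each strand had to differ by 20 points. Stricter thresholds and fewer reads call fewer tiles by construction; for the tile size the cause was not tested. Counts stayed within 1.5 times at read minimums of 20 and 100, without high-coverage CpGs and without possible base differences. Possible base differences were CpGs with at least 3 reads in both libraries, at least 80% methylated in 1 and at most 5% in the other. No base calls were used, so the rule also takes out methylation differences and can weaken tiles by construction. The thinned calls shared 652 tiles with the 1147. For the named tiles, 84 alternative values kept the call or sign, 5 lost the adjusted p, 4 moved and 3 reversed. Reversed were 9921001 on chromosome 12 (-9.52, plus strand), 54620001 on chromosome 11 (-0.448, minus strand) and 90256001 on chromosome 2 (12.5, plus strand). The adjusted p was lost at 41434001 on chromosome 15 and 31398001 on chromosome 3 without possible base differences. That rule takes out CpGs with the largest differences, so it can weaken a tile by construction. With the deeper library thinned it was lost at 114546001 on chromosome 11, 173994001 on chromosome 1 and 8528001 on chromosome 12. Only 16 of the 20 tiles had a value without possible base differences, and the largest gain and the largest loss had none. The cause was not tested. Called dense regions, 105 and 87, became 298 and 317 with at least 15 CpGs and 64 and 53 with at least 100 reads, since other regions were tested. Lost and gained CpGs, 4 and 4, became 0 and 0 at a coverage of 20, where 40514 CpGs remained, 1335 and 1124 at 5, and 7963 and 5928 at 3, where more CpGs were tested on fewer reads each. The X stretch without knockout reads kept its 2574 bp at 10 CpGs and had 0 knockout reads on the plus strand. Depth limits the tiles: at intermediate levels, simulated changes of 30 and 40 points were recovered in 42 and 82%.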

Other observations

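The tests of the plus against the minus strand, of CpG weighting and local CpG density and of mitochondrial reads were chosen after the result was seen. So were the patterns, except the called tiles, whose rules were set before. The tests of read spread, CpG weighting and local CpG density replaced earlier versions after first values were known. The window size and coverage minimum for lost CpGs were picked after several had been looked at. Methylation depended on the bases flanking the CpG, in both libraries alike. The lowest wild-type level was at ACGA and its reverse TCGT, 74.9%, and the highest at ACGC and GCGT, 79.9%. Knockout minus wild-type differences by flanking bases ran from -0.0606 points at ACGT to 0.262 points at TCGA. Among CpG-dense regions, 1.18% of 1444 on X lay between 35 and 65%, against 3.75% of autosomal regions. Among tested tiles, those of 3 to 5 CpGs had 0.915 knockout reads per wild-type read and those of 81 or more CpGs 0.85. The minimum of 50 reads per library can favour tiles of few CpGs where the shallower knockout library was deep. This trend may therefore come in part from the filter.

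The 1147 called tiles exceed the 2 unchanged tiles called in simulation with independent reads. A methylation difference between the animals, by genotype or otherwise, would be carried by both strands. Of the tiles called on the plus strand 48.7% had the same sign on the minus strand, which argues against such a difference as the main source of those tiles. The 1147 tiles were called on pooled reads, which favours agreement of the strands, so this check does not carry over to them directly. Of them, 506 differed by at least 20 points on each strand, and single tiles stay open. The strand mix of the reads is argued against too, since 6.02% of the called tiles fell under 20 points when differences were averaged within strands. Reads of neighbouring CpGs from shared fragments may account for the calls. Over 843029 tiles, differences measured on alternate CpGs of a tile correlated within a strand, with a mean r of 0.269 (standard error 0.00200), and not across strands, with an r of -0.000681 (0.000879). Fragments themselves were not told apart here, so other effects limited to a strand stay open.

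The knockout level was higher on 18 of 19 autosomes without high-coverage CpGs, by 0.0935 points in all. It was higher on 11 of 19 with each CpG weighted equally, among those with at least 5 reads in both libraries. Incomplete conversion in the knockout library is argued against by mitochondrial CpGs, where the methylated share differed by -0.000889 points. Fewer knockout reads on CpG-dense sequence may account for part of the difference, 0.0547 points (standard error 0.00672). Within classes of local CpG density 0.0388 points (0.00889) were left, so differences in reads between these classes did not account for the whole. Reads can also be spread unevenly inside a class, so the test cannot exclude the distribution of reads as the whole cause. With each autosomal CpG weighted equally the difference was 0.0130 points (0.00683) at a coverage of at least 5 and 0.0566 points (0.0144) at 10, so the weighting by reads stays open, as does genotype, which 1 library per group cannot test.

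A few windows of 1 Mb, on autosomes and on X, held more CpGs that lost methylation in the knockout library than expected. At a coverage of at least 3, 4 of 2581 windows passed the adjusted p: those starting at 175 Mb (8 lost CpGs, 1.00 expected) and 174 Mb (14, 3.98 expected) on chromosome 2, at 114 Mb on chromosome 6 (16, 4.97 expected) and at 83 Mb on X (15, 3.53 expected). For gained CpGs 3 windows passed, and at a coverage of at least 4 none passed in either direction. The adjusted p takes lost or gained CpGs as independent. Neighbouring CpGs can be read on the same few fragments, so it is too small and gathering of lost CpGs is not established. At a coverage of at least 3, the 5 windows of 1 Mb at X 72 to 75 and 82 to 84 Mb, picked after the data were seen, held 62 lost and 21 gained CpGs; at a coverage of at least 4 the counts were 17 and 4. They were picked for their lost CpGs, and 4 of them did not pass the adjusted p, so the group of 5 is weak. The autosomal windows were not weighed. Lower depth in the X windows is argued against by a ratio of knockout to wild-type reads of 0.984 relative to X, and a regional loss of methylation by a median tile difference of -0.507 points (standard error 0.313) from the rest of X. Base differences between the animals remain a candidate explanation: 90 covered CpGs within 100 bp of the lost CpGs had a median difference of 0 points (-4.05 when weighted by reads), and base calls of the animals were not analysed here. The lost CpGs did not form 1 block around the stretch without knockout reads: the window at 71 Mb, which holds it, had 5 lost CpGs (5.19 expected), and those at 75 and 81 Mb, between the picked groups, had 3 (4.25 expected) and 1 (3.26 expected).

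In 25681 windows of 100 kb, 1 had a read ratio beyond 0.5 on the log2 scale: X 166400001 to 166500000 held 36658 wild-type and 17049 knockout reads, a log2 difference of -0.90 from the autosomal median ratio of 0.865. These reads lay on 950 CpGs with high-coverage CpGs kept, far above the wild-type X mean of 4.56 reads per CpG. The ratio there is thus not that of ordinary X sequence. Mitochondrial CpGs were read at 422 times the autosomal mean in the wild-type and 470 times in the knockout library. The tile with the most reads, chromosome 2 98507001 to 98508000, held 1.44% of all wild-type and 1.59% of all knockout reads, at 88.5% and 87.2% methylated. Of the 426 dense regions at intermediate levels, 25 passed the adjusted p, 15 higher and 10 lower in the knockout library.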
